A study of Mus musculus with 2 samples.

How the data were processed

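The material was lung from mouse embryos at embryonic day 14.5, pooled from 24 embryos for replicate 1 and from 34 embryos for replicate 2, and the assay was ChIP-seq with an antibody against H3K36me3. The 2 libraries form 1 group, taken from the labels. Per the labels and the notes deposited with the samples, the authors aligned reads to mm10, filtered the alignments and called peaks against a control. The aligner, the peak caller, their versions, the threshold and the rule by which a peak counted as replicated are not given in the sources used here. The raw reads and the control were not analysed here. Because the files hold peaks and no counts, the sequencing depth of each library is unknown, and intervals that need it are not given.

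The deposited files are 4 peak lists in the narrowPeak format, and the authors made 1 list from each replicate, 1 from both replicates pooled, and 1 of replicated peaks from the other 3. The coordinates, in bases of mm10, are those the authors deposited. The signal value of each peak in the deposited lists was read as a fold enrichment over the control, because it is a ratio on a linear scale that never falls below 1. This fold is the authors' value and only ranks peaks within a list. It was used to pick the strongest replicated peaks, to describe groups of peaks within a list, to compare marker genes in the replicated list and to leave out weaker peaks in a test of the X. The −log10 p and −log10 q of each peak are also the authors' deposited values, and were used for the stricter lists and for ranking. The score that the authors deposited for each peak was not used here. Chromosomes 1 to 19, X and Y were used, and peaks on unplaced scaffolds were left out of the comparisons.

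Genes were taken from GENCODE M21, which is annotated on the same assembly, and gaps in the assembly were left out of genome shares. Coverage of a gene was the percent of its body, start to end, inside peaks, computed per replicate, for 21221 protein-coding genes of at least 1 kb. A gene was called marked at 20% or more in both replicates. Positions along genes used 10 equal parts of the body and 2 kb steps to 10 kb on each side, for genes of at least 5 kb that overlap no other gene. Promoters were 1 kb on each side of a gene start. Chance levels came from 100 shuffles of peaks within chromosomes outside gaps. Each of 38 gene lists, 22 from symbols and the others from symbol patterns, was set against 10000 random lists of the same size matched in 20 bins of gene length, by the percentile of its median. Domains joined replicated peaks at most 3 kb apart. The SD over the 2 replicates describes their spread, and no p-value was computed, since there is no second group.

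The lists, the 20% limit, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named, for each list, the 2 genes with the highest and the 2 with the lowest mean coverage, all Hox genes, the 10 most covered genes of at least 20 kb, the 10 genes of at least 5 kb with the largest difference between replicates, and the 5 longest marked and 5 longest unmarked genes. It also named Xist, the 5 most covered noncoding genes of at least 5 kb that overlap no protein-coding gene, the 10 longest domains and the 5 strongest replicated peaks. A further 18 genes, each pointed out in the text, were named after their values were seen.

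The alternatives were stricter peaks (−log10 p of at least 5, or −log10 q of at least 2), equal numbers of peaks, the replicated or the pooled list in place of the single lists, overlaps of at least 50%, limits of 10% and 40%, other gene length limits, genes that overlap no other, promoters of 2.5 kb on each side, and each replicate left out. Exons in the 3′ side alone, circular shifts as a chance level and the restriction to ubiquitous genes on the X were added after seeing the data. Shifting the second list along each chromosome gave overlaps of at most 9.05% and 7.84%.

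The code was tested on simulated data. All 87 genes made marked among 16650 were recovered with 0 false calls and a largest error of 0.291 points, 1 list made high was found, and 4 of 200 random lists passed a limit on either side. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures used matplotlib 3.10.9, and overlaps of at least 50% of both peaks were counted with bedtools 2.31.1.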

Results

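H3K36me3, a trimethylated lysine of histone H3 that lies over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse lung at embryonic day 14.5, a stage at which the airways are still branching. The 2 libraries formed 1 group of biological replicates. Replicate 1 came from tissue pooled from 24 embryos and replicate 2 from tissue pooled from 34, each with both sexes. The authors' 4 peak lists were used, 1 for each replicate, 1 for both replicates pooled and 1 of replicated peaks. They give no read counts, so the sequencing depth is unknown. The coverage of a gene is the percent of its annotated body, start to end, that lies inside peaks, and a gene was called marked when its coverage was at least 20% in each replicate's own list. It measures how far the peaks extend and not how high they are. Values after ± are SDs of the 2 replicates (n = 2), positions are in mm10, and because the design has no second tissue or stage no p-value was made.

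The first question was how much of the genome carried the mark and how far the replicates shared it. Peaks covered 98.9 Mb ± 14.0 (SD, n = 2) of sequence, 3.36% of the gap-free genome in replicate 1 and 4.11% in replicate 2. Replicate 1 had 186538 peaks and replicate 2 had 204697, with median widths of 322 and 329 bp. The covered length was 1.22 times larger in replicate 2, and still 1.17 times larger when both lists were cut to the same number of peaks. At least 1 bp of 79.7% of the replicate 1 peaks lay in a replicate 2 peak, and 65.2% of the replicate 2 peaks touched one of replicate 1. In 100 shuffles of the second list within chromosomes these shares were never above 8.60% and 7.86%. Of the union of covered bases, 51.2% was shared, against a shuffled mean of 2.15%. The shuffles did not keep peaks inside genes, so they do not give the overlap expected of lists that both lie in genes. Overlap followed the authors' p, but stronger peaks were also wider, with a median of 442 bp in both replicates at −log10 p of at least 5. Wider peaks touch more often by chance, and the chance level was not measured by strength. In the strongest 25% of each list 97.1% of the replicate 1 peaks and 94.5% of the replicate 2 peaks touched the other list, and in the weakest 25% 61.1% and 39.0% did. When at least 50% of both peaks had to overlap, the shares fell to 35.9% and 32.8%.

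The pooled list held 167482 peaks over 129.5 Mb and the replicated list 118162 peaks over 115.9 Mb. Each replicated peak had the same start and end as a pooled peak. The replicated list thus kept 70.6% of the pooled peaks (Wilson 95% interval 70.3% to 70.8%, counting error only). Kept peaks had a median width of 601 bp and a median fold enrichment of 4.03, as the authors' column gives it, and those not kept had 247 bp and 2.83. Both replicates' own lists touched 81.6% of the kept peaks and 2.14% of the others.

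The mark lay almost entirely inside genes. Annotated genes held 96.0% ± 0.16 (SD, n = 2) of the covered bases but 46.0% of the gap-free genome, a ratio of 2.09 ± 0.0035, and protein-coding genes alone held 95.2%. Exons were the most enriched class, with 25.4% of covered bases against 4.84% of the genome, a ratio of 5.24 ± 0.11. Introns held 70.7% at a ratio of 1.72 ± 0.0089. Promoters, taken as 1 kb on each side of a gene start, held 3.02% at a ratio of 0.783 ± 0.011, and sequence between genes held 3.97% at a ratio of 0.0736 ± 0.0030. Shuffled peaks of replicate 1 fell in genes for 48.5% to 49.3% of their bases and those of replicate 2 for 48.5% to 49.4%, so the genic share lay far outside the shuffled range in both replicates.

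Along genes, coverage rose from the 5′ to the 3′ end. Among 2275 marked protein-coding genes of at least 5 kb that overlapped no other gene, the first of 10 equal parts of the body was covered by 9.33% ± 1.14 (SD, n = 2), the fifth by 49.3% ± 5.4, the ninth by 62.2% ± 6.4 and the last by 58.2% ± 6.1. The 2 kb before the gene start were the least covered part, with 2.16% ± 0.22. Past the gene end, coverage was 35.0% ± 5.3 over the first 2 kb and 15.8% ± 2.3 over the next 2 kb. The 3′ side of the body had more coverage than the 5′ side in 90.8% ± 0.93 of these genes, and in 2001 of them in both replicates. Averaged with equal weight per gene, coverage was 34.6% ± 4.0 on the 5′ side and 63.6% ± 6.4 on the 3′ side. The values of the 10 parts pool bases over genes, so long genes weigh more in them and the 2 measures differ. The 6558 genes of the same kind that were not marked also rose toward the 3′ end, from 0.971% ± 0.18 to 6.72% ± 1.63.

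**Figure D1:**
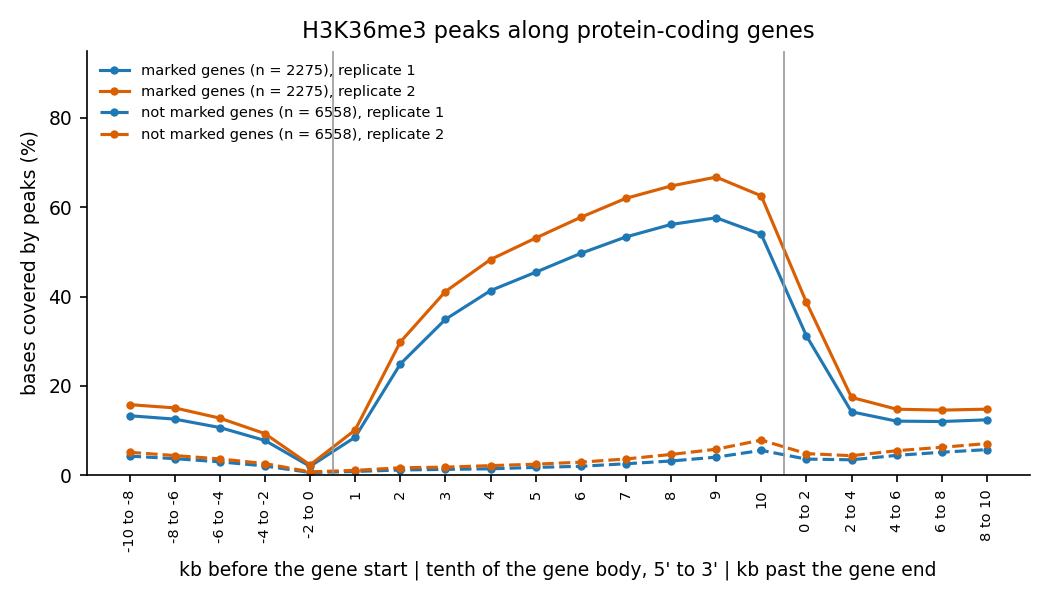
Percent of bases covered by peaks (vertical axis) in 2 kb steps before and after protein-coding genes and in 10 equal parts of their bodies (horizontal axis), for 2275 marked genes (solid lines) and 6558 genes that were not marked (dashed lines), with 1 line per replicate. In marked genes both replicates are lowest just before the gene start (mean 2.16%) and highest in the ninth part of the body (mean 62.2%).

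Pooled over marked genes, exonic bases were more covered than intronic bases. Over 5740 marked genes, 59.3% ± 5.0 (SD, n = 2) of exonic and 41.0% ± 4.7 of intronic bases lay in peaks, and the ratio of the 2 was 1.45 ± 0.044. The ratio was above 1 in each replicate, 1.48 in replicate 1 and 1.42 in replicate 2. Since coverage is highest on the 3′ side, the comparison was repeated within the 3′ side of the body, a choice made after seeing the data. There it was 67.6% ± 5.6 of exonic and 53.5% ± 5.9 of intronic bases, a ratio of 1.27 ± 0.035. Bases were summed over genes, so long genes weigh more among introns than among exons. The ratio within single genes was not measured, so differences between genes may contribute to it.

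Of 21221 protein-coding genes of at least 1 kb, 5740 (27.0%) were marked and 9553 had no peak in either replicate. Replicate 1 alone reached the 20% limit in 5808 genes and replicate 2 in 6692, with 68 genes past the limit in replicate 1 only and 952 in replicate 2 only. Across genes the coverage of the replicates correlated with a Pearson's r of 0.978 and a Spearman's rho of 0.966, a description over genes that are not independent replicates. Coverage was higher in replicate 2 for 9550 genes and higher in replicate 1 for 2113. Asking for 40% of the body in place of 20% left 3136 marked genes.

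Among genes of at least 20 kb the most covered was Kpnb1, the importin beta that carries proteins into the nucleus (chr11:97159714–97187881), at 93.1% ± 2.2 (SD, n = 2). The splicing factor genes Sf3a1 (chr11:4160350–4182541) and Sf3b3 (chr8:110810239–110846787) followed with 92.9% ± 2.0 and 90.6% ± 1.6, and Top2a, the DNA topoisomerase of dividing cells (chr11:98992943–99024189), with 91.3% ± 0.51. The chromatin remodeller gene Chd4 reached 88.4% ± 3.4. The other 5 of the 10 most covered were Rbm5, Safb2, Prpf8, Exosc10 and Sec24c, between 87.6% and 88.1%. At the other end, Cntnap2, Dmd and Ptprd, 3 of the longest protein-coding genes, had 0.0041%, 0.0044% and 0.265% of their bodies in peaks. The other 2 of the 5 longest unmarked genes were Gm20388 at 11.4% ± 1.6 and Fgfr2 at 8.29% ± 1.3, whose annotated models run across many other genes and do not describe single genes. The longest marked genes were Macf1 at 32.9% ± 1.1, Trio at 29.3% ± 7.3, Fndc3b at 29.2% ± 7.1, Syne2 at 26.8% ± 8.1 and Nf1 at 27.6% ± 4.6. Among genes of at least 5 kb the replicates differed most at Cln5, a lysosomal protein gene covered by 18.5% in replicate 1 and 56.9% in replicate 2, and at Cxcr6, a chemokine receptor gene that overlaps Fyco1, with 18.3% and 51.6%.

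Gene lists fixed beforehand were then compared with 10000 random lists of protein-coding genes of the same size and length, by the percentile of the list's median coverage. Genes that every dividing cell uses stood high, with the highest medians in the cell cycle, splicing factor, ribosomal protein, housekeeping and proteasome lists. All 33 cell cycle genes were marked, with a median of 70.6%, led by Top2a and by the condensin gene Ncapd2 at 86.9% ± 2.6 (SD, n = 2). Of 37 splicing factor genes 34 were marked, with a median of 68.7%, and the list's lowest member was Esrp1, an epithelial splicing regulator, at 4.74% ± 2.9. Ribosomal protein genes had 71 of 82 marked with a median of 62.2%, led by Rps3 at 84.6% ± 1.4, while the paralogs Rpl10l and Rpl39l had no peak. Housekeeping genes had 30 of 36 marked, led by the elongation factor gene Eef2 at 83.0% ± 2.2. The proteasome (31 of 40), mediator and RNA polymerase II (33 of 41) and nuclear genes of mitochondrial complex I (35 of 46) had medians of 55.4%, 42.7% and 33.7%. In each of these 7 lists the median lay above all or nearly all random lists, at the 100th percentile. Of the 38 lists, 12 lay in the top 2.5% of random lists and 1 in the bottom 2.5%, where chance alone would place 0.95 lists on each side. A list whose median was 0, as in 18 cases, could rarely be placed low, because many random lists had a median of 0 too.

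The list of writers, erasers and readers of H3K36 methylation was itself mostly marked, 28 of 35, with a median of 49.3% at the 100th percentile. It also holds genes of transcription elongation factors, so these values are not those of writers, erasers and readers alone. Kdm4a, a demethylase of this residue (chr4:118136957–118180043), was covered by 85.2% ± 3.3 (SD, n = 2) and Brpf3, a scaffold of acetyltransferase complexes, by 77.9% ± 1.6. Setd2, the main H3K36 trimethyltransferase (chr9:110532597–110618633), had 49.8% ± 1.2 and the methyltransferase gene Nsd1 65.3% ± 4.5. Kdm4d had no peak. Setd2 and Nsd1 were chosen after their values were seen.

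**Figure D2:**
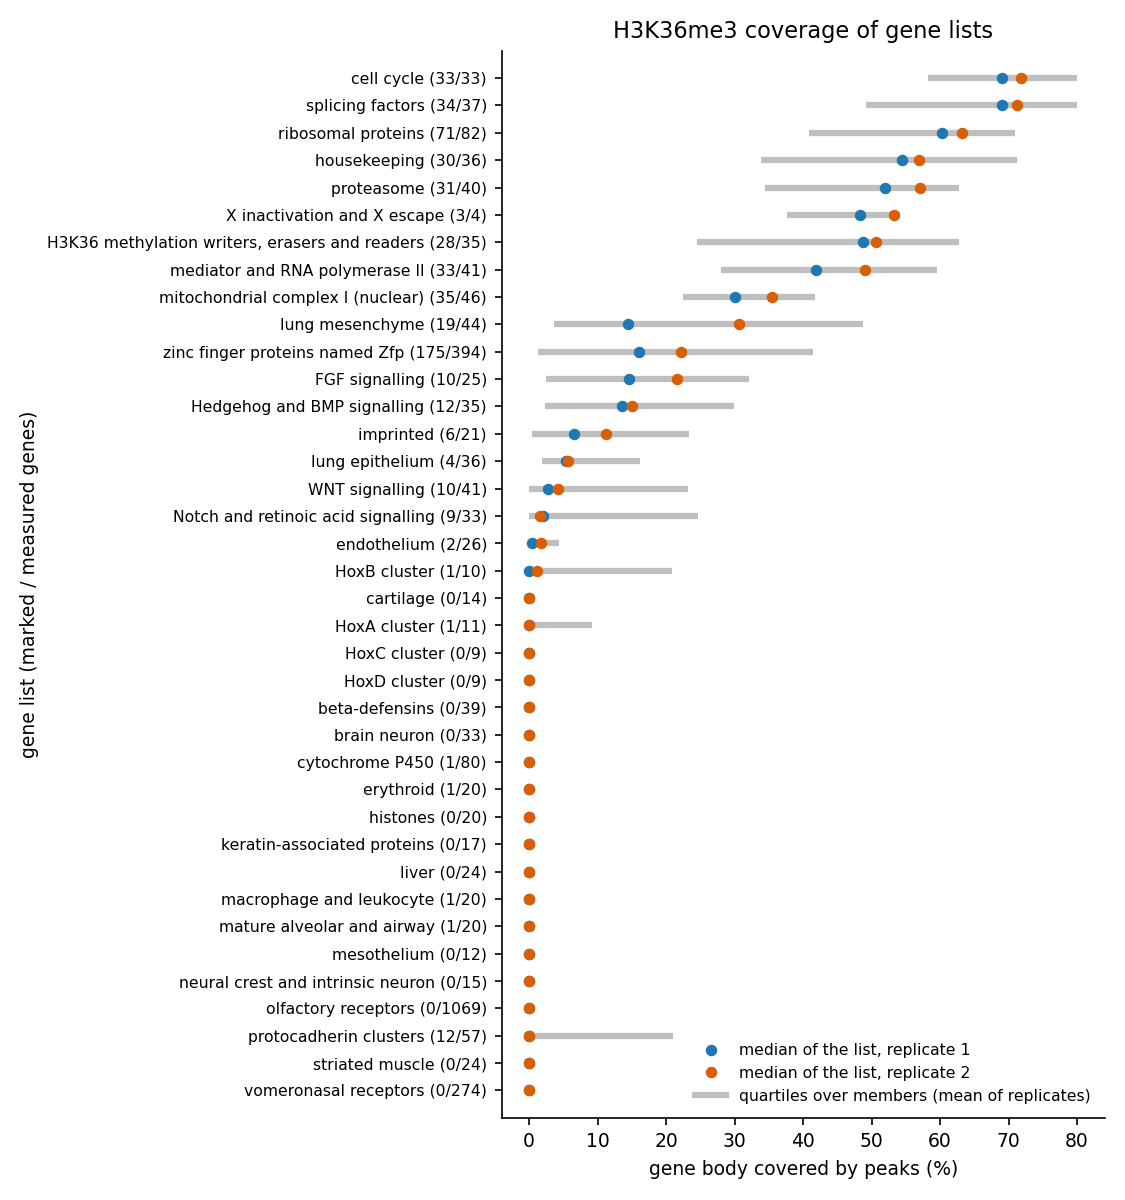
Percent of the gene body covered by peaks (horizontal axis) for each of 38 gene lists (vertical axis, with the number of marked and measured genes), as the median of the list in replicate 1 (blue) and replicate 2 (orange), with grey bars for the quartiles over members of the mean coverage. Cell cycle genes lead with a median of 70.6%, lung mesenchyme markers stand at 21.8% and lung epithelium markers at 5.81%.

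A further question was which cell types of the lung the mark showed. Markers of the lung mesenchyme were marked in 19 of 44 cases with a median of 21.8%, at the 99.99th percentile of random lists. The most covered were Col1a1, a chain of type I collagen (chr11:94936224–94953042), at 82.8% ± 1.8 (SD, n = 2) and the fibronectin gene Fn1 (chr1:71585520–71653200) at 80.9% ± 3.4. The T-box factor genes Tbx5 (chr5:119832668–119885219) and Tbx4 (chr11:85886422–85916097), active in lung mesenchyme, had 69.6% ± 8.0 and 57.5% ± 5.7. Ptch1, the Hedgehog receptor (chr13:63508328–63573598), had 74.0% ± 0.67, Gli1, a Hedgehog-responsive factor, 48.7% ± 2.8, the forkhead factor gene Foxf1, which lies inside the long gene model Gm20388, 54.7% ± 5.6 and the growth factor receptor gene Pdgfra 53.1% ± 12.3. Fgf10, the ligand for distal budding (chr13:118669791–118792115), had 0.223% ± 0.11 of its body in peaks, and Twist1 had no peak. Tbx5, Tbx4, Gli1, Foxf1 and Pdgfra were chosen after their values were seen. The mesenchymal median was 14.5% in replicate 1 and 30.6% in replicate 2.

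Markers of the lung epithelium were marked in 4 of 36 cases with a median of 5.81%, at the 93.7th percentile. The 4 were Gata6, an endodermal zinc finger factor (chr18:11052064–11085635), at 59.7% ± 2.7 (SD, n = 2), the forkhead gene Foxp4 at 46.4% ± 8.4, the FGF-responsive factor gene Etv5 at 39.0% ± 10.6 and Mycn at 37.9% ± 1.8. Nkx2-1, the factor that specifies the lung (chr12:56531958–56536908), was covered by 16.7% ± 2.2 and Sox9, a factor of the distal tips, by 6.73% ± 0.064, both under the limit. In the replicated and the pooled list Nkx2-1 passed the limit, with 24.7% and 32.6%, and Sox9 did not, with 5.53% and 12.9%. Hopx and Rbpjl had no peak. Etv5, Mycn, Nkx2-1 and Sox9 were chosen after their values were seen. Fgfr2 counted as unmarked, over a model that runs across many other genes. Each replicate taken alone gave 6 marked epithelial genes and the pooled list 11, while a limit of 40% left 2.

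Markers of other cell types did not stand above random lists, with list medians between the 7.95th percentile for the mesothelium and the 40.9th for the endothelium. The mesothelial, leukocyte, erythroid, neural crest and mature alveolar lists had a median of 0, the lowest possible. Many random lists had a median of 0 too, so this comparison could not place these lists low. Of 26 endothelial markers 2 were marked, Eng at 29.3% ± 3.4 (SD, n = 2) and Egfl7 at 20.3% ± 0.022, and both overlap other protein-coding genes. None of the 21 endothelial markers that stand alone was marked, and Cldn5 and Emcn had no peak. No mesothelial (0 of 12), neural crest and neuronal (0 of 15) or cartilage (0 of 14) marker was marked. Among 20 macrophage and leukocyte markers the 1 marked was Cd68 at 82.9% ± 21.6, which lies beside Eif4a1, a translation factor gene, chosen after its values were seen, that was covered by 71.0% ± 0.89. Among 20 erythroid markers the 1 marked was Tfrc, the transferrin receptor used by all dividing cells, at 54.4% ± 0.30. Of 20 markers of mature alveoli and airways 1 was marked, the phospholipid enzyme gene Lpcat1 (chr13:73467197–73516422), at 48.5% ± 1.1, while the water channel gene Aqp5 had no peak.

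Genes of the signalling pathways of lung branching were marked in part. The FGF list had 10 of 25 marked with a median of 17.4% at the 97.1th percentile, led by Hras at 65.0% ± 0.43 (SD, n = 2) and the receptor gene Fgfr3 at 58.8% ± 9.6, while the ligand genes Fgf1 and Fgf7 had no peak and Fgfr2 counted as unmarked over its overlong model. Its coverage over a shorter model was not measured. The Hedgehog and BMP list had 12 of 35 marked with a median of 15.5% at the 99.6th percentile, led by Ptch1 and by the inhibitor Smad7 at 50.6% ± 4.3. The WNT list had 10 of 41 marked with a median of 3.47%, led by the WNT-responsive gene Axin2 at 66.3% ± 6.3 and the coreceptor gene Lrp5 at 44.2% ± 6.5. Ctnnb1, the beta-catenin gene, chosen after its values were seen, had 43.1% ± 1.5, and the antagonist genes Dkk1 and Dkk2 had no peak. The Notch and retinoic acid list had 9 of 33 marked with a median of 1.70%, led by the retinoid receptor gene Rxrb at 59.4% ± 5.8 and Notch3 at 55.5% ± 5.9. The WNT and Notch lists, at the 59.1th and 51.8th percentiles, did not stand apart from random lists. With a limit of 40% the 4 pathways had 3, 5, 2 and 2 marked genes, and without replicate 1, or from the pooled list, the FGF median rose into the top 2.5%.

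The Hox clusters, whose genes are used in order along the body axis, were covered over a few genes of HoxA and HoxB. In the HoxA cluster Hoxa5 (chr6:52201754–52204587), needed for lung development, was the 1 marked gene of 11, with 43.9% ± 11.1 (SD, n = 2), and it lies inside the annotated body of Hoxa3. Hoxa2, Hoxa3 and Hoxa4 had 17.0% ± 24.0, 9.75% ± 3.3 and 8.59% ± 12.2, and Hoxa1, the most 3′ gene, and Hoxa6 to Hoxa13 had no peak. In the HoxB cluster Hoxb3 (chr11:96323326–96347930) was the 1 marked gene of 10, with 34.7% ± 10.7. Hoxb4 had 22.1% ± 4.6, Hoxb5 21.2% ± 14.5 and Hoxb2 19.8% ± 2.2, each under the limit in replicate 1, and Hoxb1, the most 3′ gene, Hoxb7, Hoxb8, Hoxb9 and Hoxb13 had no peak. None of the 9 HoxC and 9 HoxD genes had a peak in either replicate. Replicate 2 alone gave 2 marked HoxA and 4 marked HoxB genes, and replicate 1 alone 1 of each.

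**Figure D3:**
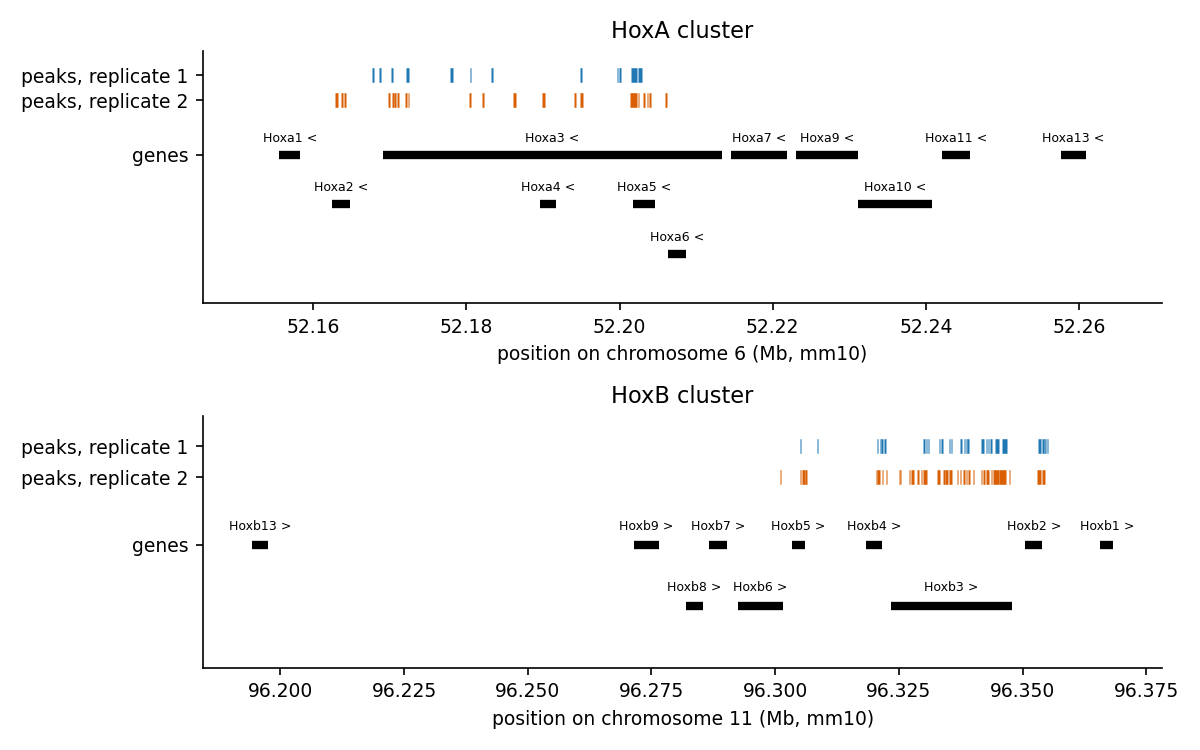
Maps of the HoxA cluster on chromosome 6 and the HoxB cluster on chromosome 11 with 10 kb on each side (horizontal axis, position in Mb, mm10), with annotated genes in black, arrowheads for their strand, and peaks of replicate 1 (blue) and replicate 2 (orange). Peaks of both replicates lie around Hoxa5 (mean coverage 43.9%) and across Hoxb3 (34.7%), and none lies over Hoxa7 to Hoxa13 or Hoxb7 to Hoxb13.

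Several large gene families and the genes of other tissues had almost no peaks. Of 1069 olfactory receptor genes none was marked and 1068 had no peak in either replicate, the exception being Olfr543 with 1.72% ± 2.4 (SD, n = 2). All 274 vomeronasal receptor, 17 keratin-associated and 39 beta-defensin genes had no peak, and the vomeronasal list fell in the bottom 2.5% when limited to genes of at least 5 kb. None of 24 liver, 24 striated muscle or 33 brain genes was marked, and 23, 20 and 31 of them had no peak. Apart from these, histone genes of at least 1 kb were not marked (0 of 20). Of 80 cytochrome P450 genes, enzymes of drug and steroid metabolism, 1 was marked, Cyp2t4 at 31.7% ± 6.7, which overlaps Egln2. This was the 1 list in the bottom 2.5% of random lists, at the 1.54th percentile, but it left it with either replicate alone, with −log10 p of at least 5, in the replicated and pooled lists and among genes that overlap no other. The protocadherin clusters had 12 of 57 marked, led by Pcdhgc4 at 51.6% ± 10.3, but the gamma genes share their 3′ exons and overlap each other, so the 12 are not 12 separate signals. Replicate 2 alone gave 21. The median of the list was 0, at the 8.985th percentile, but among genes of at least 5 kb the list lay in the top 2.5%.

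Zinc finger genes with Zfp symbols, many of them repressors of the KRAB type, had 175 of 394 marked with a median of 18.8% at the 100th percentile. Zfp869 (chr8:69706332–69710724) led with 85.9% ± 1.9 (SD, n = 2), followed by Zfp606 (chr7:12478293–12496235) with 83.8% ± 1.2. A further 80 had no peak, among them Zfp114 and Zfp119b.

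Imprinted genes, expressed from one parental copy, were marked in 6 of 21 cases with a median of 9.02% at the 87.0th percentile. Igf2r (chr17:12682406–12769664) led with 72.0% ± 8.2 (SD, n = 2). Nnat, which overlaps Blcap, followed with 44.7% ± 20.6, while Magel2 and Ndn had no peak. Of the 16 imprinted genes that overlap no other protein-coding gene 3 were marked. Among noncoding genes of at least 5 kb that overlap no protein-coding gene, 27 of 4226 were marked. The most covered were Snhg17, a host gene of small nucleolar RNAs (chr2:158353700–158361580), at 75.3% ± 7.1, 5430416N02Rik at 70.3% ± 8.4, the abundant nuclear RNA Malat1 (chr19:5795690–5802672) at 70.3% ± 0.24, 1700020I14Rik at 62.5% ± 2.7 and the imprinted Meg3 (chr12:109541001–109571726) at 54.97% ± 16.8. Xist, the RNA that silences an X chromosome in females and whose body overlaps a coding gene model, had 2.80% ± 1.4 of its body in peaks.

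By chromosome, the X stood apart. Peaks covered 0.632% ± 0.11 (SD, n = 2) of the X and 4.08% ± 0.58 of the autosomes, a ratio of 0.154 ± 0.0045, and 60 of 877 X genes (6.84%) were marked against 5680 of 20181 autosomal genes (28.1%). Restricted to the 7 lists of ubiquitous genes, a choice made after seeing the data, 4 of 11 X members were marked against 258 of 299 autosomal members (86.3%). The 4 were Rps4x at 57.2% ± 6.9, Med12 at 51.7% ± 10.5, Rpl39 at 41.1% ± 0.49 and Pgk1 at 29.8% ± 9.3, and Hprt, a housekeeping gene of purine salvage, had 13.1% ± 0.11. These 5 genes were chosen after their values were seen. Of 4 X genes known to escape X inactivation 3 were marked, Kdm5c (chrX:152233020–152274535) at 56.9% ± 8.3, Ddx3x (chrX:13280970–13294052) at 53.2% ± 2.5 and Eif2s3x at 48.6% ± 4.3, while Kdm6a had 4.995% ± 0.53. Among the autosomes chromosome 11 was the most covered, 6.99% ± 0.88 with 34.7% of its genes marked, and chromosome 3 the least, 2.70% ± 0.36. None of 163 Y genes was marked. The share of X genes marked was 2.62% with stricter peaks (−log10 p of at least 5), 1.82% with a limit of 40%, 11.6% with a limit of 10% and 11.7% in the pooled list.

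**Figure D4:**
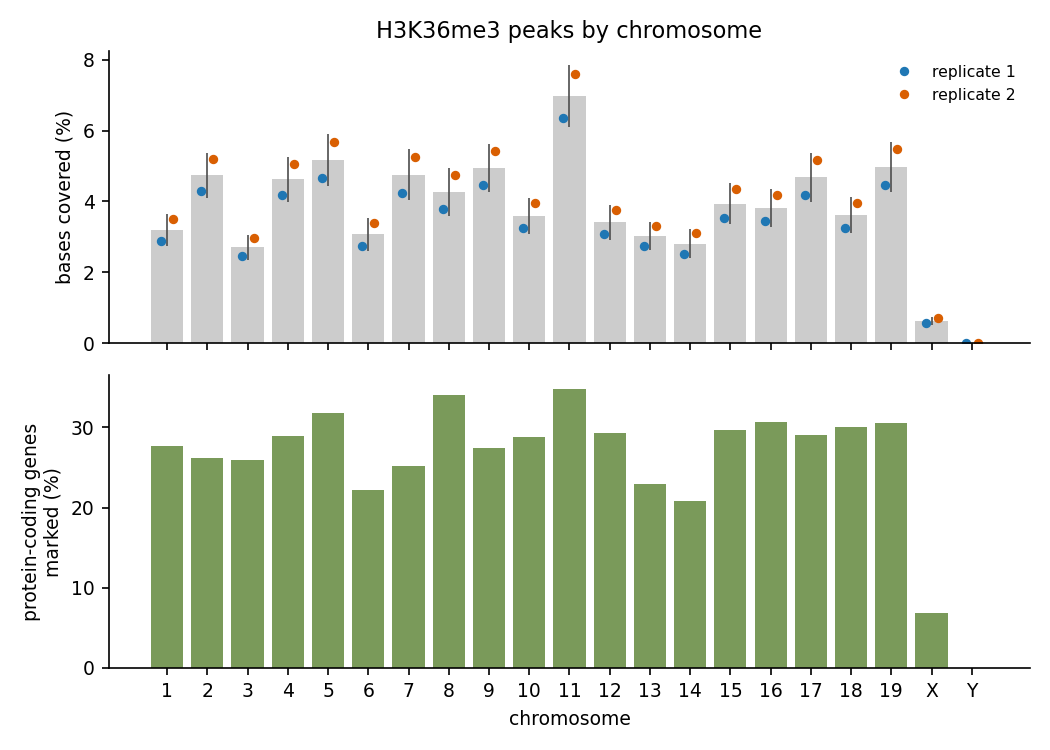
Percent of the bases of each chromosome covered by peaks (upper axis, bars for the mean, lines for the SD of 2 replicates, points for each replicate) and percent of its protein-coding genes of at least 1 kb called marked (lower axis), with gaps in the assembly left out. The X stands at 0.632% of bases and 6.84% of genes, and chromosome 11 at 6.99% and 34.7%.

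Replicated peaks at most 3 kb apart joined into 19827 domains with a median length of 3357 bp, of which 5318 were at least 10 kb and 363 at least 50 kb long. The longest, 201.9 kb, lay on the fibrillin gene Fbn2 (chr18:58006731–58208636), and peaks of replicate 1 covered 64.6% and those of replicate 2 71.3% of it. The next lay on Usp34 and Ahsa2 (chr11:23344210–23496586), on Myh10 and Ndel1 (chr11:68696515–68845164), on Chd2 (chr7:73424775–73555669) and on Wdfy3 (chr5:101831819–101961946), between 130.1 and 152.4 kb. Col27a1, another matrix gene, held one of 117.4 kb. By the authors' fold enrichment the strongest replicated peak, at 16.37, lay over Zfp865, Ccdc106 and the gene model Gm44973 (chr7:5027363–5034071) and was 75.7% exonic. It was followed by peaks in Gnas (14.3), Tpm1 (13.8), Ddx17 (13.6) and Brd2 (13.3).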

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

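The tests of escape genes on the X and of lists matched on coverage and gene length, and that of the typical fold of marker genes, were chosen after the result was seen.

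Peaks on unplaced scaffolds were left out of the comparisons, and they drew attention because a signal lay there that no comparison used. Replicate 1 had 11 peaks and replicate 2 had 11 on 3 scaffolds and so more than the 3 that a count of 0 would allow, a bound that any few called peaks pass and that does not measure signal. Their highest fold enrichment was 8.08 in replicate 1 and 11.7 in replicate 2, and 6 peaks stood in the replicated list. No explanation was tested for them.

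The X chromosome was less covered than the autosomes, and the values argue against its gene content as the whole cause. The 11 X members of the ubiquitous lists had a median coverage of 13.1%, while length-matched draws of autosomal members had 57.1% (95% of draws 30.3% to 69.4%). How large a part gene content plays over the other X genes was not measured. A single active X copy under a fixed peak threshold could halve the signal and lose peaks, and it cannot be told apart from other causes here. When autosomal members kept only peaks of at least 2 times the low end of fold, their median was 45.0% (15.7% to 62.9%), still 31.9 points above the X (a difference of −31.9), but dropping whole peaks does not mimic a weaker signal. The escape genes, read from both X copies in females, had a median of 50.9%, above 100% of draws of other X members (4.69% to 46.4%), which may point to copy number, though there were 4 of them against 11 and lengths were not matched. Sexes were pooled within each replicate, so neither was tested between the sexes, and no other biological explanation was tested.

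Replicate 2 covered more of the genome, and the number of peaks is not the whole cause, because with equal numbers the ratio of covered lengths was still 1.17 against 1.22. Whether a uniform difference in enrichment or depth accounts for it cannot be told here. After the replicates were matched by rank, the largest median residual of 18 lists was −4.28 points, for splicing factors. It lay within the 5 points set beforehand, although 5 lists lay outside the central 99% of draws of like coverage. Matching by rank removes an overall difference whatever its cause. The bound of 5 points is also close to the difference itself, a median of 6.46 points in marked genes. Splicing factors differed by a median of 2.00 points before matching. With draws of like coverage and length 4 lists lay outside the central 99%, where chance gives 0.18 lists. They were housekeeping, cell cycle, splicing factors and ribosomal proteins. The draws were not matched on the height of peaks, so they cannot decide whether a uniform difference acted on these lists. The replicates belong to 1 group, so no biological explanation was tested.

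Fewer epithelial than mesenchymal markers were marked. Among markers of 5 to 100 kb the gap was still 30.9 points (4 of 23 against 14 of 29), so markers outside this range are not its whole cause. Lengths were not matched inside the range, so it cannot be told here whether gene length contributes. The strictness of the call also leaves a gap of 26.0 points, with 16 of 36 against 31 of 44 markers covered by at least 10% in the pooled list. A smaller share of epithelial cells could lower the enrichment of each peak, but it cannot be told apart from other causes here, because the median highest fold, 0.709 times as high in epithelial as in mesenchymal markers (4.13 over 25 genes against 5.82 over 40, resampled 95% interval 0.619 to 0.971), rose with the number of peaks in a gene (Spearman's rho 0.671) and left out the 11 epithelial markers without a replicated peak. The median fold of a gene's peaks was 0.956 times as high (0.822 to 1.03). Lower transcription of these genes per cell was not tested, and the design has no sorted cells in which to test it.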

How the results depend on the processing

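The test of exons in the 3′ side alone was chosen after the result was seen. No paired analysis was possible because there is only 1 group. No list called high or low changed to the opposite call. The protocadherin list, not called at the 8.985th percentile, was called high among genes of at least 5 kb.

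With −log10 p of at least 5 the covered length was 78.9 Mb (98.9 Mb as reported), the replicated share of pooled peaks 87.4% (70.6%), the genic ratio 2.0926 (2.0855), the X to autosome ratio 0.115 (0.154) and Spearman's rho 0.952 (0.966). With −log10 q of at least 2 the X ratio was 0.146 and rho 0.961, with equal numbers of peaks rho was 0.965, and with genes of at least 5 kb 0.974. Overlap fell from 72.5% to 60.4% when 50% of a peak had to be covered and to 34.3% when 50% of both had to be. The share of genes more covered on the 3′ side was 87.1% in genes of at least 20 kb and 89.6% with overlapping genes kept (90.8%). A limit of 40% left 3136 marked genes (5740). The X ratio was 0.175 in the pooled list. The exon to intron ratio was 1.51 in the replicated list, 1.498 in the pooled list and 1.27 in the 3′ side (1.45). Lists in the bottom 2.5% numbered 0 with −log10 p of at least 5, in the replicated and pooled lists and with genes that overlap no other, and 2 with genes of at least 5 kb (1), where vomeronasal receptors became low and protocadherins high (13 high lists against 12). The FGF list became high in the pooled list and without replicate 1. Fewer peaks, stricter overlaps and a higher limit lower counts by construction, and for the rest the cause was not tested.

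With each replicate left out the genic ratio was 2.083 to 2.088, the 3′ share 90.1% to 91.0%, marked genes 5808 to 6692, high lists 12 to 13, low lists 0 to 0, the X ratio 0.151 to 0.158 and the exon to intron ratio 1.48 to 1.51.

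Over all alternatives, calls of named genes were the same in 2411 cases, gained in 59 and lost in 36, and calls of lists were the same in 444, gained in 4 and lost in 6. Apart from these and from the values given above, the classes of annotation, the shared share of bases and the shares of X and autosomal genes marked were compared. Of these values 39 stayed within the bound used for them, such as the SD of the replicates or, for shares of genes marked, 1.5 times. The other 19 did not or had no bound. The shared share of bases had no bound and was counted among the 19. It was 49.8% with −log10 p of at least 5, 50.7% with −log10 q of at least 2 and 51.7% with equal numbers of peaks (51.2%). The depth is unknown, so what it limits could not be measured.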

Other observations

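The tests of zinc finger genes and of domains outside genes were chosen after the result was seen.

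Zinc finger genes stood out among the strongest peaks. Of the 100 replicated peaks with the highest fold enrichment in protein-coding genes, 18 touched a Zfp gene, against 2.01% of all 113010 such peaks. The comparison was not matched on width, and wider peaks touch a gene more often. The 5 strongest replicated peaks were 3221 to 15678 bp long, against a median of 601 bp in the replicated list. In the 175 marked Zfp genes the last exon was covered by 67.9% ± 3.3 (SD, n = 2) and the body by 43.7% ± 3.9. In 5565 other marked genes these were 59.8% ± 5.4 and 44.5% ± 4.8. The median last exon was 2795 bp long in the marked Zfp genes and 1298 bp in the other marked genes. In the 219 Zfp genes that were not marked, the last exon was covered by 18.5% ± 3.5 and the body by 5.24% ± 1.2. Last exons of other unmarked genes were not measured, so this is not shown to be particular to Zfp genes. Reads shared between paralogs were not measured, because the files hold no alignments.

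Few domains lay outside annotated genes. Of the 19827 domains 269 (1.36%) touched no annotated gene, and 33 of these were at least 2 kb long. Of the 33, 11 held a gene in a second annotation, 10 began within 10 kb past the end of a marked gene and 5 lay within 10 kb before the start of one. The longest (chrX:101462862–101476266) was among the 11.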
